A study of Gallus gallus with 18 samples.

How the data were processed

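Total RNA from 18 samples of the bursa of Fabricius, labelled male and taken at 80 days of age, was hybridised as biotin-labelled cRNA to an Affymetrix chicken gene-level array with 1 colour, per the labels' protocols. The table deposited by the authors holds 1 log2 expression value per probe set and array. The log2 scale was read from the values, whose highest, 15.1, lies under the ceiling of a 16-bit scanner on that scale. The submitters' processing notes name GCOS 1.1.1. Background correction, summarisation and normalization are not given in the sources used here, and array medians of 7.56 to 8.04 show that the arrays do not share a single distribution. No value is missing, and 0.684% of values are below 0, down to -15.8, so folds of dim probe sets are large and uncertain. No detection call or signal over background was used here.

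Of 20804 probe sets, 12300 carried a single gene symbol in the platform annotation, 256 several and 8248 none. Entrez identifiers matched 11727 of the 12300 to RefSeq genes of the assembly bGalGal1.mat.broiler.GRCg7b, which was used only for names, Z and W membership and gene order, and 573 kept the symbol of the array. These name 11528 distinct genes, represented by the probe set with the highest mean level. Of probe sets with identical values, 895 repeated an earlier one, the first of each set not counted, and 855 of the 895 were unnamed.

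Groups were taken from the title codes, since the breed field and the initials of the codes name different breeds for FL, CF, RR and PR. Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 2.07 prior degrees of freedom), so that all groups share 1 estimate of the spread. Contrasts were PD against MS, FL against RR, CF against PR, each group against the mean of the other 5, all 15 pairs, each candidate cross against the mean of its parents, and an F test over the groups. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast.

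Before the data were examined, the contrasts above and 40 gene lists were fixed for cell types, pathways and breed traits, of which 39 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and members were counted over all genes and adjusted over the list alone. Genes to be named were fixed by rule at the same time, only from probe sets with a single symbol. For pairs of groups these were up to 12 each way that passed with ranges that did not overlap, for each group against the rest up to 6 each way, for a cross up to 5 each way and for the F test the 15 largest. Where none passed, the 5 with the smallest p were named as not passing. Up to 6 list members by smallest p, all members of the EDN3 region, 6 pigmentation genes and the W genes were added. PMEL and MLANA, 2 of the pigmentation genes, were not analysed here. Further probe sets are marked as chosen after their values were seen.

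The sex label was checked with 14 W genes and with 498 Z against 10510 autosomal genes. The Z genes were also tested as a list with camera, chosen after the data were seen and not among the 40 fixed lists. Between groups that differ in arrays high in HINTW its direction could be foreseen, so its p-values are no separate support. An array counted as high in HINTW above a log2 level of 9, set after the values were seen. Correlations across arrays used 100000 permutations. The model was tested on simulated data with 20804 probe sets, 50 changed at each size. For PD against MS it recovered 2, 38, 72 and 96% of changes of 0.5, 1, 2 and 4 log2 units with 4 false calls, and for PD against the rest 4, 56, 80 and 96% with 10 false calls. With nothing changed it made 0 calls in either. The gene lists, run on the 11528 named genes of the same simulation, also gave 0 calls. Values were drawn independently for each probe set and array. The simulation therefore could not show false calls, of probe sets or of lists, that come from correlated genes or from a structure of the samples. Its shares and counts may not hold for the real arrays, where another split into groups gave 2015 calls for PD against the rest.

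Other settings fixed in advance were an intensity trend, array weights, quantile normalization, centring on array medians, leaving out the dimmest 30% of probe sets, averaging the probe sets of a gene, the replicate number as a block, fits of the compared groups alone, adjustment over all 15 pairs together, and leaving out each array in turn. Settings chosen after seeing the data were adding 16 before log2, the HINTW level or the cell cycle list mean as a covariate, leaving out Z and W probe sets, using probe sets with identical values once, leaving out the 9 arrays high in HINTW, and quantile normalization for the gene lists. Leaving out those 9 arrays picks samples by a measured level, and it was kept only to give values without arrays whose signal goes against the male label. A fit of the 9 high arrays alone, which picks samples in the same way, was also run and is not reported. Up to 100 splits of the arrays into groups of the same sizes, the real one included, were used for each count.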

Results

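Transcript levels in the bursa of Fabricius, the organ in which bird B cells mature and diversify their antibody genes, were measured at 80 days of age in chickens of Thai indigenous breeds and in Rhode Island Red birds. The 18 arrays fell into 6 groups of 3, named here by their title codes PD, FL, MS, CF, RR and PR. The breed field gave Pradhuhangdum for PD, Rhode Island Red for FL, Mae Hong Son for MS, a cross of Pradhuhangdum with Rhode Island Red for CF, FhaLuang for RR and CheeFah for PR. The initials of the codes would instead place FhaLuang at FL, CheeFah at CF, Rhode Island Red at RR and the cross at PR, so groups are compared by code and no breed is assigned to FL, CF, RR or PR. Nothing in the labels said whether the 3 arrays of a group came from separate birds, so p-values measure only the spread between these samples, which may be technical. Each array held 20804 probe sets with median levels of 7.56 to 8.04 on the log2 scale. Arrays of the same group correlated at 0.839 to 0.947 (median 0.89) and arrays of different groups at 0.788 to 0.94 (median 0.874), in each case across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

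All 18 samples carried the label male, and the female-specific W chromosome was read as a check of that label. HINTW, a gene present in many copies on the W chromosome and absent from the male genome, stood at 11.45 to 12.54 in 9 arrays and at 5.09 to 5.88 in the other 9. The high arrays were PD2, FL1, FL3 and all 3 arrays of MS and of CF, and none of the 3 arrays of RR or of PR was among them. ATP5F1AW, the W copy of the ATP synthase alpha subunit gene, had its lowest value in the same 9 arrays at 8.94 and its highest value elsewhere at 7.06. Male birds carry a pair of Z chromosomes and females a single copy. Each gene was taken as its deviation from its own mean over the 18 arrays, so signs are relative to the other arrays. The median deviation of 498 Z genes differed from that of 10510 autosomal genes by -0.28 to -0.13 log2 units in the 9 high arrays. In the other 9 arrays the same difference ran from 0.06 to 0.35. Groups therefore differed in W and Z signal as well as in breed, and the share of high arrays is given with each group. HINTW stood at 11.90 in PD2 against 5.84 and 5.34 in PD1 and PD3, and at 5.09 in FL2 against 11.97 and 12.02 in FL1 and FL3. The arrays of PD and of FL were therefore not repeats of a single RNA sample, and their spread was not technical alone.

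**Figure D1:**
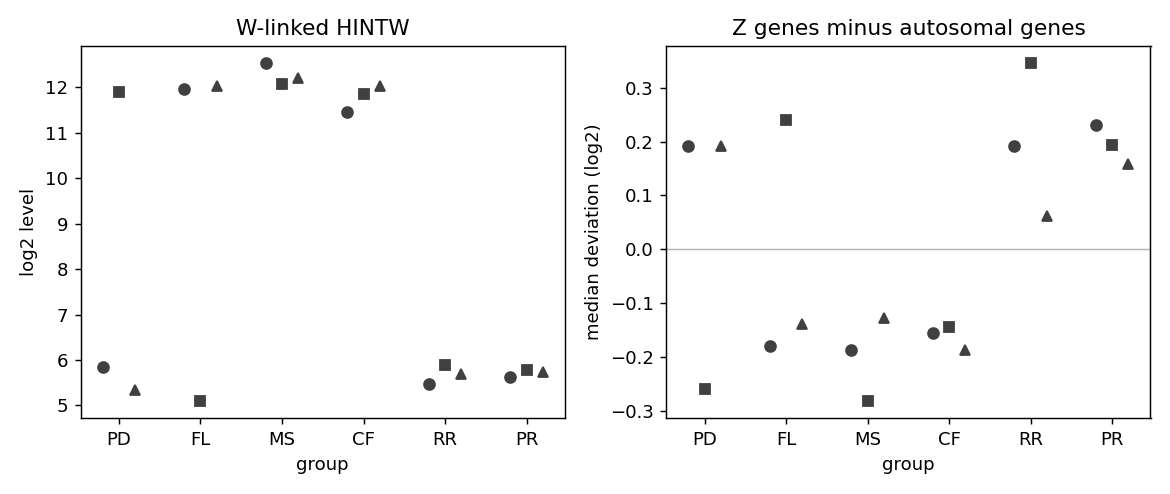
Level of the W-linked gene HINTW (left, log2) and median deviation of Z genes minus that of autosomal genes (right, log2) for each of the 18 arrays by group, with circles, squares and triangles for replicates 1, 2 and 3. The 9 arrays with HINTW at 11.45 or above all lie below 0 on the right, and the 9 arrays at 5.88 or below all lie above 0.

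Which genes differed among the 6 groups at all was asked first. SLC7A9, a subunit of a transporter of cystine and dibasic amino acids, ranged from 4.92 ± 0.14 (SD, n = 3) in MS to 6.94 ± 0.12 in PD (limma, adjusted p = 0.0278). DBX2, a homeobox transcription factor gene, ranged from 6.00 ± 0.33 in PD to 7.99 ± 0.15 in PR (adjusted p = 0.0278). ATP5E, the epsilon subunit of mitochondrial ATP synthase, ranged from 8.61 ± 0.12 in MS to 10.16 ± 0.35 in RR (adjusted p = 0.0286). These were 3 of the 5 probe sets that passed the moderated F test, against 2505 (12.04%) at an unadjusted p under 0.05. The other 2, outside the rule for named genes and chosen after their values were seen, were an unnamed probe set (15394835) and a probe set of PCF11. Of the 15 genes with the largest F, 6 lay on the Z chromosome, among them ACAA2, PTCD2, DCTN3 and MRPL50 (adjusted p = 0.121 to 0.125), and 1 on the W chromosome. The calls of SLC7A9, DBX2 and ATP5E ended when the HINTW level was a covariate (adjusted p = 0.0604, 0.206 and 0.206) and with the replicate number as a block (adjusted p = 0.069, 0.0809 and 0.0816), and that of SLC7A9 with an intensity trend (adjusted p = 0.0612). Of the 18 fits that left out 1 array they passed in 11, 12 and 8 (adjusted p up to 0.131, 0.0942 and 0.0895). SLC7A9 and DBX2, at mean levels of 5.62 and 6.63, were dim, and leaving out the dimmest 30% of probe sets removed both.

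PD and MS were the only groups whose title code and breed field named the same breed, Pradhuhangdum against Mae Hong Son. SLC7A9 was higher in PD by 2.02 (log2, SE 0.229, limma, adjusted p = 0.0084), 4.06-fold, and no other probe set passed, against 1086 (5.22%) at an unadjusted p under 0.05. Its probe set was dim (4.92 in MS), and without the dimmest 30% of probe sets, which removed it, none passed. Epithelial markers stood lower in PD, with 33 of 38 negative and a median of -0.35, while extracellular matrix and fibroblast genes stood higher, with 26 of 27 positive and a median of 0.66. The p-values were 0.159 and 0.307 with an estimated correlation, after adjusted p = 1.89e-06 and 0.000137 in camera with its preset correlation. No member of either list passed over all genes or adjusted over the list alone. Mean deviations of the matrix list were 1.05, -0.63 and 0.03 in PD1, PD2 and PD3 against -0.65, -0.66 and -0.23 in MS1, MS2 and MS3. PD1 thus stood apart, and PD2 lay among the MS arrays. COL1A2, LUM and COL6A3, matrix genes, differed by 1.32, 1.51 and 1.36 without passing. Heat shock genes were positive in 27 of 28 (median 0.25, p = 0.05 and adjusted p = 0.964 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were positive in 50 of 53 (median 0.26, p = 0.245 with an estimated correlation). ATP5I, COX7C and NDUFS4, at differences of 0.80, 0.77 and 0.59 in that list, are Z genes, and the median of all measured Z genes was 0.37 against 0.11 for autosomal genes (camera p = 2.13e-10, p = 0.13 with an estimated correlation). PD held 1 and MS 3 arrays high in HINTW. In a fit of the PD and MS arrays alone SLC7A9 did not pass (adjusted p = 0.118). With HINTW as a covariate it differed by 1.92 (adjusted p = 0.329), and the matrix list turned to the opposite direction (adjusted p = 0.859). The epithelial call was lost without MS3 (adjusted p = 0.104) and the matrix call without PD1 or MS1 (adjusted p up to 0.464). SLC7A9 lost its call without MS1 or MS2, with an adjusted p of up to 0.0841 and differences of 1.96 to 2.10 over all 18 fits that left out 1 array.

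FL against RR compared FhaLuang with Rhode Island Red under either reading of the labels, without settling which was which. Neuron and glia markers stood lower in FL, with 16 of 17 negative, a median of -0.67 and adjusted p = 2.97e-11 (camera; p = 0.00915 with an estimated correlation, adjusted p = 0.357). Their mean deviations were 0.83 in RR1 and 1.61 in RR2, but -0.30 in RR3 lay among -0.33, -0.07 and 0.30 in the FL arrays. Smooth muscle (0.83, 0.89 and -0.85 in RR1, RR2 and RR3), endothelial (0.51, 0.73 and -0.75) and adipocyte and lipid storage markers (0.68, 0.76 and -0.50) were likewise high in RR1 and RR2 and low in RR3. CHGA, which encodes chromogranin A of neuroendocrine granules, was the only member lower adjusted over the list alone (-1.03, SE 0.204), and none was over all genes (adjusted p = 0.121 for CHGA). Skeletal muscle markers were negative in 22 of 27 (median -0.40, p = 0.107 with an estimated correlation), a call lost without RR1 (adjusted p = 0.202). All 44 cell cycle genes were positive (median 0.96 against 0.20 over all probe sets, p = 0.59 with an estimated correlation), a call lost without FL1 or RR2 (adjusted p up to 0.239) and turned to a passing call in the opposite direction without RR1 (adjusted p = 0.0206). With HINTW as a covariate that list took the opposite direction (adjusted p = 0.887). Of genes of antibody gene diversification and linked DNA repair 26 of 27 were positive (median 0.57, p = 0.412 with an estimated correlation), a call lost without FL1 (adjusted p = 0.0919), without RR1, where the direction turned (adjusted p = 0.817), and with HINTW as a covariate (adjusted p = 0.699). Among named genes none passed over all genes. ATP5E differed by -1.16 (SE 0.197, adjusted p = 0.0571), TMIGD1, an epithelial adhesion molecule gene, by -2.32 (adjusted p = 0.0773), ATM, a DNA damage kinase gene, by 0.75 (adjusted p = 0.111) and MIR1708 by 1.42 (adjusted p = 0.132). The single probe set that passed was the unnamed 15394835, at 4.42 ± 2.97 in FL against -7.29 ± 0.56 in RR, among the dimmest values on the array, against 2337 (11.2%) at an unadjusted p under 0.05. FL held 2 and RR 0 arrays high in HINTW, and without the 9 high arrays, which left 1 array of FL assumed to vary like the other groups, 12 probe sets passed.

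CF against PR compared CheeFah with the cross under either reading of the labels. Interferon response genes stood higher in CF, with 35 of 40 positive and a median of 0.68, and 27 members were higher adjusted over the list alone against 0 over all genes. IFIT5, an antiviral RNA-binding protein gene, differed by 3.06 (SE 0.561), SAMD9L by 2.43, DDX60 by 2.64 and RSAD2, which encodes viperin, by 2.21. The list passed in camera (adjusted p = 1.14e-18; p = 0.0125 and adjusted p = 0.243 with an estimated correlation) and in fry, which asks only whether its genes moved (adjusted p = 0.0198). EDN3, the gene of endothelin 3, a growth signal for pigment cell precursors, was lower in CF by 1.89, a log2 difference of -1.89 (SE 0.256, adjusted p = 0.0353). DBX2 was also lower in CF (-1.65, SE 0.244, adjusted p = 0.0442).

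All 7 measured genes of the EDN3 region of chromosome 20, which is duplicated in birds with fibromelanosis, a hyperpigmentation of skin and internal organs, were negative in CF against PR (median -0.70). EDN3, ATP5E, PRELID3B and ZNF831 were lower adjusted over the list alone and EDN3 over all genes (camera adjusted p = 4.09e-08, p = 0.00937 and adjusted p = 0.243 with an estimated correlation; fry adjusted p = 0.0148). All 44 cell cycle genes were negative in CF (median -1.04) and all 20 T cell markers positive (median 0.76), with p = 0.271 and 0.231 with an estimated correlation and no member passing adjusted over either list alone. B cell genes were negative in 18 of 23 (median -0.53) without passing (adjusted p = 0.0761). The T cell call ended with the cell cycle list mean as a covariate (adjusted p = 0.238). All 13 cholesterol synthesis genes were negative (median -0.86, p = 0.0963 with an estimated correlation), with STARD4, a Z-linked sterol carrier gene, lower adjusted over the list alone (-1.30). Oxidative phosphorylation genes were negative in 48 of 53 (median -0.30, p = 0.139 with an estimated correlation). Of the 5 lower adjusted over that list alone, ATP5I, COX7C, NDUFS4 and ATP5F1AZ were Z genes and ATP5E lay in the EDN3 region, and the single higher member was the W gene ATP5F1AW. CF held 3 and PR 0 arrays high in HINTW, and the median over all Z genes was -0.30 against 0.02 over autosomal genes (camera p = 6.04e-16, p = 0.0606 with an estimated correlation).

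In all, 5 probe sets passed between CF and PR, 1 higher and 4 lower in CF (2 and 3 with arrays centred on their medians), against 2090 (10%) at an unadjusted p under 0.05. EDN3 lost its call without FL3, MS1, MS2, CF1, CF3 or PR2 (adjusted p up to 0.19), while its difference stayed at -2.05 to -1.72, and with HINTW as a covariate (adjusted p = 0.328). Neither EDN3 nor DBX2 passed with the replicate number as a block (adjusted p = 0.167 and 0.181), adjusted over all 15 pairs together (0.0558 and 0.103), in a fit of the CF and PR arrays alone (0.109 and 0.0761) or with the cell cycle list mean as a covariate (0.0603 and 0.106). DBX2 did not pass with HINTW as a covariate (-1.30, adjusted p = 0.401), and leaving out the dimmest 30% of probe sets removed it. Of 18 fits that each left out 1 array DBX2 passed in 7, those without PD2, PD3, FL2, MS3, RR1, RR2 or PR1 (adjusted p up to 0.199 in the others), with differences of -1.80 to -1.57.

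**Figure D2:**
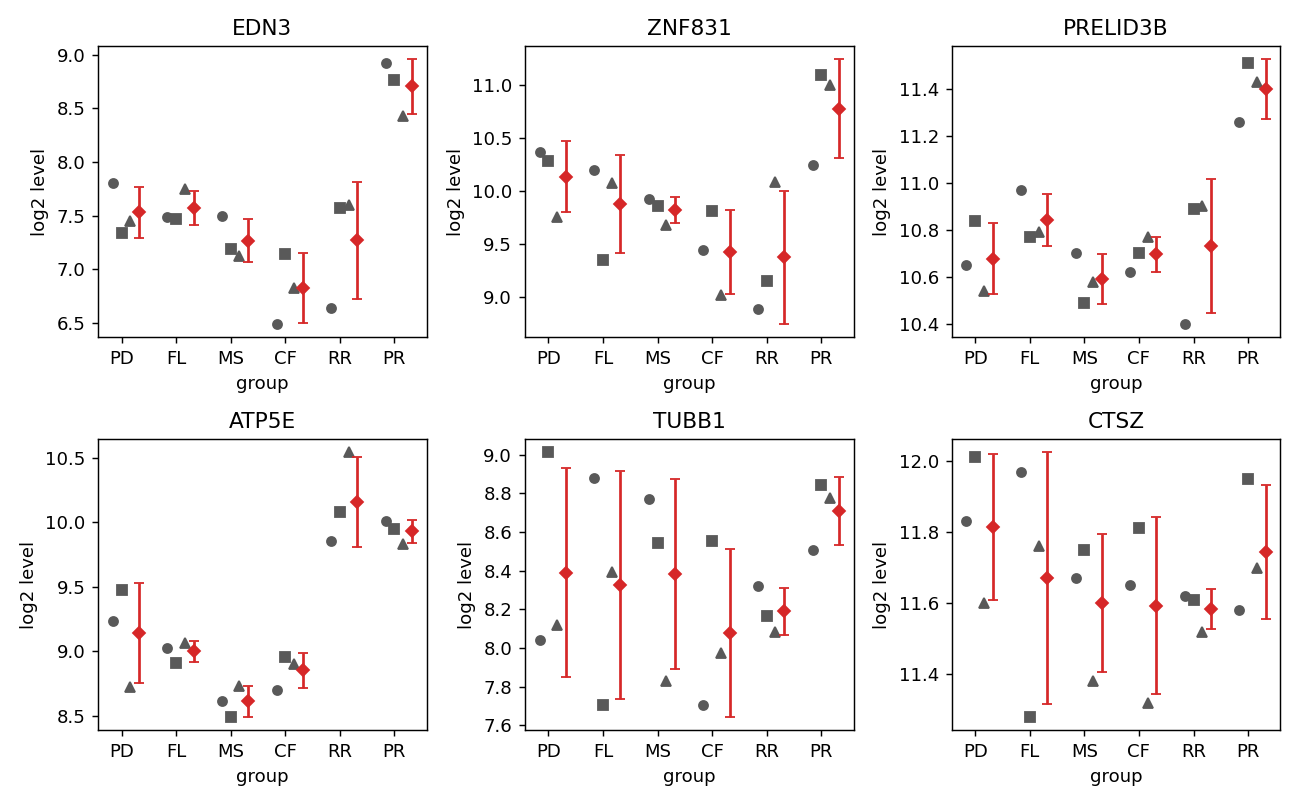
Levels (log2) of EDN3 and 5 genes that follow it on chromosome 20 in each array by group, with circles, squares and triangles for replicates 1, 2 and 3 and a red diamond with a bar for the group mean ± SD of 3 arrays. EDN3 reached 8.71 ± 0.26 in PR against group means of 6.82 to 7.57 elsewhere, while ATP5E was high in RR (10.16) as well as in PR (9.93).

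Each group was then set against the mean of the other 5. The genes of the EDN3 region had mean deviations of 0.36, 0.71 and 0.53 in PR1, PR2 and PR3, above every other array (up to 0.30). EDN3 rose by 1.42 (SE 0.198, adjusted p = 0.0168), 2.67-fold, and DBX2 by 1.63 (SE 0.189, adjusted p = 0.011). DECR1, a mitochondrial enzyme gene of unsaturated fatty acid oxidation, fell by 0.96 (SE 0.128, adjusted p = 0.0157) and TMEM17, a membrane protein gene of the primary cilium, by 0.93 (SE 0.147, adjusted p = 0.0383). MIR1580, dim in PR at -4.37 ± 5.51 against 3.92 to 4.55 elsewhere, passed at an adjusted p of 0.0491. Its difference of -8.55 shrank to -1.05 with 16 added before log2, and the call ended (limma, adjusted p = 0.26). Other members of the region differed by 1.06 for ZNF831, 0.69 for PRELID3B, 0.78 for ATP5E, 0.44 for TUBB1, 0.09 for CTSZ and 0.02 for NELFCD. With EDN3, the first 3 of these were higher adjusted over the list alone and EDN3 over all genes (camera adjusted p = 6.24e-13; p = 0.00171 and adjusted p = 0.0665 with an estimated correlation).

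Of 20 measured genes of pigmentation, 5 were higher and 1 lower in PR adjusted over the list alone and 0 over all genes. Mean deviations of this list were 0.295, 0.14 and 0.03 in PR1, PR2 and PR3, and PD1 (0.283) and RR1 (0.284) lay above PR2 and PR3. DCT (0.73), TYR (0.81) and TYRP1 (0.96) encode enzymes of melanin synthesis and EDNRB2 (0.54) an endothelin receptor of bird pigment cells, and their mean levels in PR ran from 5.21 for TYR to 7.16 for EDNRB2. The list had a median of 0.04, and its call in camera (adjusted p = 2.3e-05) was lost with an estimated correlation (p = 0.0343, adjusted p = 0.446) and without the dimmest 30% of probe sets (adjusted p = 0.39). All 40 interferon response genes were negative in PR (median -0.46), 22 of them lower adjusted over the list alone and 0 over all genes, with IFIT5 at -2.37, SAMD9L at -1.72 and RNF213 at -1.58 (camera adjusted p = 5.04e-16; p = 0.0186 and adjusted p = 0.363 with an estimated correlation). The list's mean deviations were -0.25, -0.65 and -0.78 in PR, and that of MS2 (-0.48) lay below PR1. Interferon genes were not the only immune list low in PR1, PR2 and PR3. Macrophage genes stood at -0.13, -0.27 and -0.32 and lysosome genes at -0.26, -0.28 and -0.33. Heterophil genes stood at 0.15, -1.64 and -0.86, while MHC genes went the other way at 0.17, 0.17 and 0.24. Skeletal muscle markers were positive in 24 of 27 (median 0.30, p = 0.136 with an estimated correlation), but their mean deviation was 1.70 in PR1, -0.36 in PR2 and -0.29 in PR3. Without PR1 the call ended and the direction turned (adjusted p = 0.464).

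No PR array was high in HINTW, and Z genes had a median of 0.14 in this comparison against -0.10 for autosomal genes (camera p = 7.32e-18, p = 0.0478 with an estimated correlation). The comparison gave 14 probe sets, 5 higher and 9 lower, against 2029 at an unadjusted p under 0.05, with 10 higher and 8 lower after quantile normalization. EDN3 lost its call without PR1 (adjusted p = 0.0685) and DECR1 without PR3 (adjusted p = 0.0689). Over the fits without 1 array they differed by 1.31 to 1.56 and by -1.01 to -0.87. TMEM17 passed only without MS2, CF1, CF2, RR2 or RR3 (adjusted p up to 0.12) and MIR1580 only without PR2 (adjusted p up to 0.272). With HINTW as a covariate none of the 5 genes passed (EDN3 1.41, adjusted p = 0.229; DBX2 1.42, adjusted p = 0.147). TMEM17 and MIR1580 also lost their calls with the replicate number as a block (adjusted p = 0.0702 for each). Leaving out the dimmest 30% of probe sets removed DBX2 and MIR1580.

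Against the rest, neuron and glia markers were positive in RR in 16 of 17, with a median of 0.60. CHGA (0.88), SOX10 (0.74), the neuropeptide genes GAL (1.96) and VIP (1.14), and TH (2.22), which encodes the rate-limiting enzyme of catecholamine synthesis, were among 8 members higher adjusted over the list alone and 0 over all genes. The list passed in camera (adjusted p = 2.27e-12; p = 0.00693 and adjusted p = 0.27 with an estimated correlation), and its mean deviation was 0.83 in RR1, 1.61 in RR2 and -0.30 in RR3. TMIGD1 rose by 2.42 (SE 0.324) and ATP5E by 1.05 (SE 0.153), both at an adjusted p of 0.0405. Matrix and fibroblast genes were positive in 23 of 27 (median 0.36, p = 0.227 with an estimated correlation) and B cell genes negative in 21 of 23 (median -0.41, p = 0.317 with an estimated correlation). Their mean deviations were 1.11 and -1.19 in RR1, 0.65 and -0.27 in RR2, and -0.86 and 0.50 in RR3. Both calls ended without RR1 (adjusted p = 0.725 and 0.739, the B cell list in the opposite direction) and with HINTW as a covariate (adjusted p = 0.764 and 0.3), and the B cell call also without RR2 (adjusted p = 0.181). In all 4 probe sets passed, 2 higher and 2 lower (2 higher and 0 lower after quantile normalization), against 1898 at an unadjusted p under 0.05. The 2 lower ones, unnamed and chosen after their values were seen (15382013 and 15382677, -1.75 each), shared every group mean and SD. They are not separate findings. Of the 18 fits that left out 1 array, TMIGD1 passed in those without PD3, FL2, FL3, RR1, RR3 or PR1 and ATP5E in those without PD3, RR1 or PR1 (adjusted p up to 0.1 and 0.138 in the others), at 1.91 to 2.69 for TMIGD1 and 0.86 or more for ATP5E. No RR array was high in HINTW. Neither gene passed with HINTW as a covariate (adjusted p = 0.509 and 0.238), with arrays centred on their medians (adjusted p = 0.0512 for each) or with array weights (adjusted p = 0.101 for each), nor ATP5E with the replicate number as a block (adjusted p = 0.149). Without RR1 the count was 102.

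In CF against the rest all 44 cell cycle genes were negative (median -1.06, p = 0.344 with an estimated correlation) and so were 52 of 53 oxidative phosphorylation genes (median -0.34, p = 0.184 with an estimated correlation). Of the latter, 7 were lower adjusted over the list alone and 0 over all genes, among them the Z genes NDUFS4 (-0.64), ATP5I (-0.58), COX7C (-0.59) and ATP5F1AZ (-0.71). Interferon response genes were positive in 34 of 40 (median 0.41), with 9 higher adjusted over the list alone, SAMHD1 (0.99), EPSTI1 (0.97), DDX60 (1.64) and IRF7 (0.78) among them, and 0 over all genes (p = 0.0513 with an estimated correlation). T cell markers were positive in 19 of 20 (median 0.51, p = 0.189 with an estimated correlation) and epithelial markers in 33 of 38 (median 0.42, p = 0.213 with an estimated correlation). With the cell cycle list mean as a covariate the T cell and epithelial calls ended (adjusted p = 0.206 and 0.127). In none of these 5 lists did the 3 CF arrays lie beyond all others. Cell cycle mean deviations were -1.40, -0.02 and -1.17 in CF1, CF2 and CF3, with RR1 lower at -2.16. B cell genes, negative in 18 of 23 (median -0.62) without passing (adjusted p = 0.129), had deviations of -0.61, -0.03 and -0.53 in the same arrays. Deviations of oxidative phosphorylation genes were -0.30, -0.06 and -0.32, with PR1 lower at -0.45. Interferon deviations were 0.36, 0.72 and 0.12, T cell 0.40, 0.37 and 0.52, and epithelial 0.34, 0.28 and 0.43, against 0.45, 0.69 and 0.54 in MS3. All 3 CF arrays were high in HINTW, and Z genes had a median of -0.25 against -0.08 for autosomal genes. No gene of the naming rule passed. XPA, a Z-linked gene of nucleotide excision repair, differed by -1.41 (SE 0.214, adjusted p = 0.0846), VIT, a matrix protein gene, by -2.32 (adjusted p = 0.115), ACAA2, a Z-linked gene of fatty acid oxidation, by -0.79 (adjusted p = 0.115), GJB5 by 0.65 (adjusted p = 0.119) and ADRA2A by 0.76 (adjusted p = 0.135). The 2 probe sets that passed, against 3493 (16.8%) at an unadjusted p under 0.05, were an unnamed one (15380845, -2.61) and one of PCF11 (-4.46), both named after their values were seen.

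Epithelial markers in PD against the rest were negative in 34 of 38 with a median of -0.50 (camera adjusted p = 3.67e-15; p = 0.0409 and adjusted p = 0.932 with an estimated correlation), none of which passed adjusted over the list alone. Their mean deviations were -0.78 in PD1 and -0.87 in PD2 but 0.17 in PD3. B cell genes were positive in 22 of 23 (median 0.52, p = 0.242 with an estimated correlation), with CR2, a complement receptor gene of B cells, higher adjusted over the list alone (0.93, adjusted p = 0.451 over all genes), and all 44 cell cycle genes were positive (median 0.68, p = 0.545 with an estimated correlation), a call lost without PD2 (adjusted p = 0.609). With the cell cycle list mean as a covariate the B cell call ended (adjusted p = 0.253). SLC7A9 rose by 1.58 (SE 0.177, adjusted p = 0.00731), the only probe set to pass against 1633 at an unadjusted p under 0.05 (1 higher and 2 lower after quantile normalization). It lost its call without PD1 (adjusted p = 0.0622), with differences of 1.52 to 1.64 over the fits without 1 array, and leaving out the dimmest 30% of probe sets removed it and left 0 calls. Of the 3 PD arrays 1 was high in HINTW.

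In MS against the rest, matrix and fibroblast genes were negative in 26 of 27 (median -0.59, p = 0.116 with an estimated correlation), all 15 smooth muscle genes (median -0.61, p = 0.0921) and all 16 endothelial genes (median -0.44, p = 0.142) were negative, and 24 of 28 heat shock genes were (median -0.16, p = 0.0184, adjusted p = 0.719), each p with an estimated correlation, where none of the 4 calls held. No member of these 4 lists passed adjusted over its list alone. Mean deviations in MS1, MS2 and MS3 were -0.65, -0.66 and -0.23 for the matrix list, -0.59, -0.79 and -0.08 for smooth muscle and -0.21, -0.84 and -0.02 for endothelium. RR3 lay lower than MS3 in each, at -0.86, -0.85 and -0.75. All 3 MS arrays were high in HINTW, and with HINTW as a covariate the calls of the matrix and smooth muscle lists ended (adjusted p = 0.419 and 0.194). Limma found 0 probe sets, against 965 (4.64%) at an unadjusted p under 0.05. The genes nearest to passing were ATP5E (-0.80), the Z genes TBCA (-1.07) and MRPL50 (-0.69), SCN4B (-0.62) and SLC7A9 (-0.84), each at an adjusted p of 0.727.

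Skeletal muscle markers in FL against the rest were negative in 24 of 27 (median -0.34, p = 0.0624 with an estimated correlation), among 15 lists that passed in camera. Their mean deviations of -0.55, -0.14 and -0.23 in FL1, FL2 and FL3 lay within the range of the other arrays, of which PR1 (1.70), RR1 (1.57) and PD2 (0.83) were highest. Of the 3 FL arrays 2 were high in HINTW. In this comparison the median over all probe sets was itself 0.17, and camera ranks a list against the other genes, so the macrophage, heterophil, complement, immediate early, matrix, erythroid, breed trait, lysosome and ribosome lists were called lower with a median or a mean above 0. MIR1708 (1.21), LIPML5 (1.45), ENPP6 (1.08), CCN3, a matricellular protein gene (1.18), and FAM131B (0.69) came nearest to passing, each at an adjusted p of 0.428. The 2 probe sets that passed, 15394835 (11.37) and 15505531 (1.32), had no gene name, against 1913 probe sets at an unadjusted p under 0.05.

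**Figure D3:**
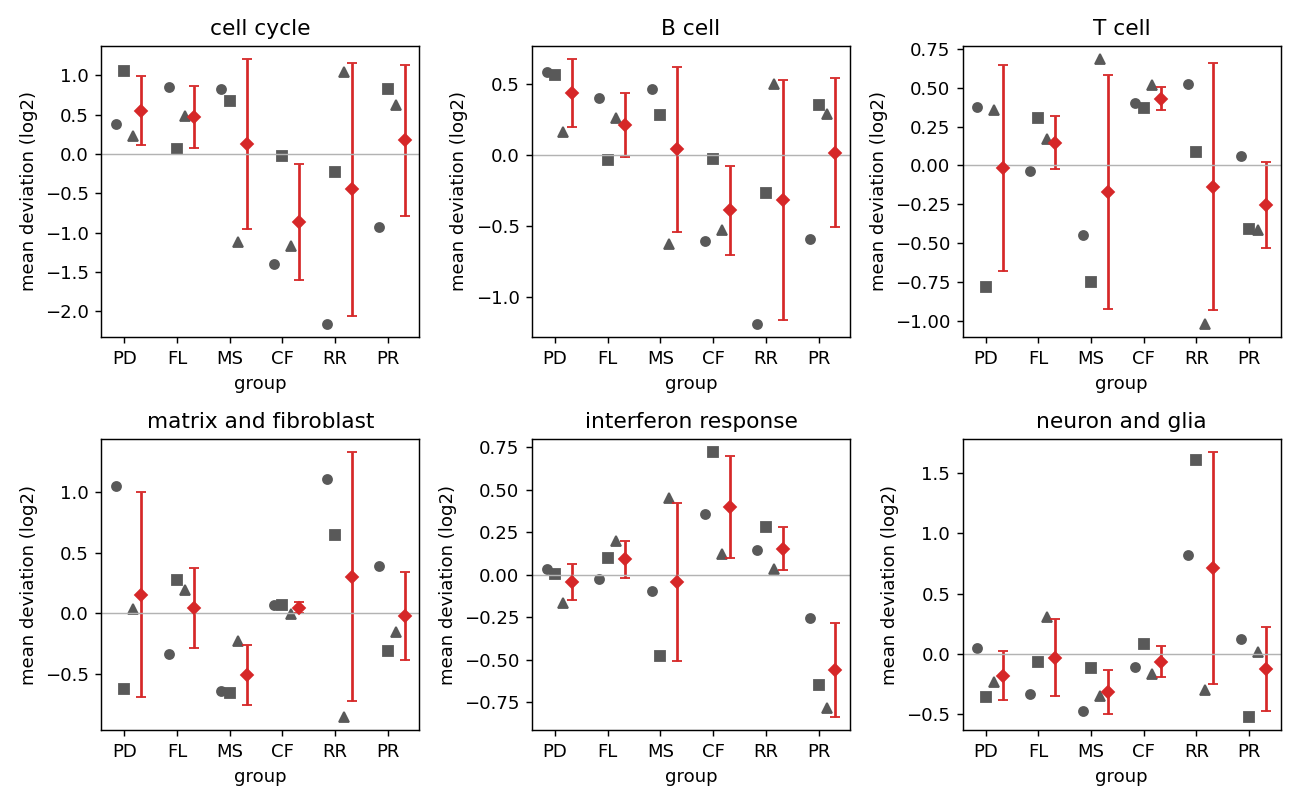
Mean deviation (log2) of the genes of 6 lists from their mean over all arrays, per array and group, with circles, squares and triangles for replicates 1, 2 and 3 and a red diamond with a bar for the group mean ± SD of 3 arrays. Interferon response genes lie below 0 in all 3 PR arrays (-0.25 to -0.78), and the cell cycle list ranges from -2.16 to 1.04 within RR.

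Over the 9 comparisons above, 131 of 351 list tests passed in camera with its preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.0665) and 4 in fry, the interferon and EDN3 region lists in CF against PR and in PR against the rest. In 13 of the 131 the test had the opposite sign to the median or the mean of the list. Besides the FL lists named above, these were the erythroid and oxidative phosphorylation lists in FL against RR, and in PR against the rest the mitochondrial ribosome list (median -0.04, mean 0.01) and the oxidative phosphorylation list (median 0.05, mean -0.14), where the W gene ATP5F1AW stood at -11.4. That value is uncertain, since its levels were -8.5 and -7.6 in PR1 and PR2 but 6.1 in PR3.

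The labels named a cross of Pradhuhangdum and Rhode Island Red, which was CF by the breed field and PR by the initials, and each candidate was set against the mean of its parents. PR differed from the mean of PD and RR by 1.42 in DBX2 (SE 0.211, adjusted p = 0.0384), by -1.40 in SLC7A9 (SE 0.198, adjusted p = 0.0312) and by -1.01 in DECR1 (SE 0.143, adjusted p = 0.0312), among 9 probe sets, 4 higher and 5 lower (6 and 3 with arrays centred on their medians), against 1578 at an unadjusted p under 0.05. None of the 3 genes passed in a fit of the PD, RR and PR arrays alone (adjusted p = 0.51 for each) or with the replicate number as a block (adjusted p = 0.0988 for each), nor SLC7A9 with an intensity trend (adjusted p = 0.0524). Leaving out the dimmest 30% of probe sets removed SLC7A9 and DBX2. With 1 array left out DBX2 passed only without FL3 or RR2, SLC7A9 only without PD2, FL1, FL3, MS3, RR1, RR3 or PR1, and DECR1 only without PD2, FL3, MS3, RR1 or PR1 (adjusted p up to 0.113). CF differed from the mean of PD and FL in 3 probe sets, all lower, against 5988 (28.8%) at an unadjusted p under 0.05. XPA (-1.46, adjusted p = 0.0641), XPNPEP3 (-0.63, adjusted p = 0.0874), ACAA2 (-0.86, adjusted p = 0.0874), SNCAIP (-2.25, adjusted p = 0.103) and MIR1618 (1.16, adjusted p = 0.103) came nearest among named genes. XPA, ACAA2 and SNCAIP are Z genes, and CF held 3 arrays high in HINTW, PD 1 and FL 2.

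Across all 15 pairs of groups the calls summed to 39. FL against PR gave 11, PD against PR 9, CF against PR 5, PD against CF 4 and FL against CF 3, and the remaining 10 pairs gave 0 or 1 each.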

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

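Chosen only after the result was seen were 16 added before log2, the HINTW level and the cell cycle list mean as covariates, leaving out Z and W probe sets, probe sets with identical values used once, leaving out the 9 arrays high in HINTW, and quantile normalization for the gene lists. Except where stated, the cause was not tested. Counts below are of probe sets that passed and differ by over 1.5 times from those of the report. With an intensity trend the F test gave 3, FL against RR 0, FL against the rest 0, PR against the rest 23, CF against the mean of PD and FL 8 and PR against the mean of PD and RR 5. With array weights, which ran from 0.26 for RR3 to 7.08 for PR3, the F test gave 9867, CF against PR 8755, PD against the rest 6, CF against the rest 7924, RR against the rest 0, PR against the rest 5582, the 15 pairs 31001, CF against its parents 8978 and PR against its parents 2869. Quantile normalization gave 0 for FL against RR, 10 for CF against PR, and 3, 0, 5 and 2 for PD, FL, CF and RR against the rest. Centring gave 1 for FL and 0 for RR against the rest. Without the dimmest 30% of probe sets the F test gave 3, PD against MS 0, FL against RR 14, and PD, FL, CF and PR against the rest 0, 0, 1 and 22. With the mean of the probe sets of a gene, which tests fewer features, FL against RR gave 0, CF against PR 3, FL, CF, RR and PR against the rest 0, 1, 2 and 5, the 15 pairs 19, and CF and PR against their parents 1 and 3. With 16 added before log2 the F test gave 8, FL against RR 18, PD, FL, CF and PR against the rest 4, 0, 1 and 24, the 15 pairs 66, and CF and PR against their parents 13 and 14. With HINTW as a covariate PD against MS gave 0, CF against PR 2, FL, RR and PR against the rest 1, 0 and 3, the 15 pairs 17 and CF against its parents 1. With the cell cycle mean as a covariate the F test gave 9, CF against PR 1, FL, RR and PR against the rest 1, 2 and 49 and PR against its parents 19. Fits of the compared groups alone gave 2 for PD against MS, 26 for CF against PR, 4169 for CF and 2 for PR against their parents. Without the 9 arrays high in HINTW, FL against RR gave 12 and PR against its parents 0, from fewer samples. Adjusted over all 15 pairs together, CF against PR gave 1 and the pairs 18. Leaving out Z and W probe sets, or using identical values once, moved no count by over 1.5 times.

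Replicate numbers did not pair arrays across groups. After group means were removed, arrays with the same number correlated at -0.344 to 0.273 (mean -0.0261, against 0.0131 for other pairs). For 4 of 18 arrays the mean correlation with arrays of other groups was highest for their own number. With the replicate number as a block the F test gave 2, FL against RR 3, CF against PR 1, FL against the rest 1, the 15 pairs 21, and CF and PR against their parents 7 and 0.

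Leaving out each array in turn, the F test gave 2 to 23 probe sets. The count was 2 without MS1 or CF3, 3 without PD1 or CF1, 8 without CF2, 9 without PR2, 10 without FL2 or MS3, 11 without PR3, 13 without RR3, 23 without RR1. PD against MS gave 0 to 6. Single values were 0 without MS1 or MS2, 2 without PR3, 3 without PD1 or PD2, 4 without PD3, 6 without MS3. FL against RR gave 1 to 19. This was 2 without FL2, 3 without FL1, MS2 or PR2, 6 without RR3, 8 without MS1, 16 without PR1, 19 without RR1. CF against PR gave 1 to 22. It was 1 without FL3, MS1, MS2, CF1 or CF3, 3 without PD1, 8 without FL2, 9 without PR3, 10 without MS3, 22 without PR1. PD against the rest gave 1 to 7. The count was 2 without PD1 or MS1, 3 without PD2 or CF2, 7 without PD3. FL against the rest gave 1 to 3, and 1 without each array except FL1 and FL2. MS against the rest gave 0 to 5. Single values were 1 without PR3, 3 without CF2, 5 without MS3. CF against the rest gave 1 to 6. This was 1 without CF1, 5 without CF2, 6 without RR1. RR against the rest gave 0 to 102. It was 0 without PD1, PD2, FL1, MS1, MS2, MS3, CF1, CF2, PR2 or PR3, 1 without RR2, 2 without CF3, 11 without PR1, 28 without RR3, 102 without RR1. PR against the rest gave 7 to 35. The count was 7 without PD1, FL3 or CF3, 8 without PD2, FL1 or MS2, 9 without MS1, CF2 or RR1, 22 without PR1, 35 without PR2. The 15 pairs gave 16 to 380. Single values were 16 without FL3, 18 without CF3, 21 without MS2, 23 without MS1, 24 without CF1, 62 without MS3, 80 without RR3, 85 without PR2, 92 without PR1, 380 without RR1. CF against its parents gave 1 to 15. This was 1 without CF1, 5 without RR2, 6 without PD3, FL1 or PR2, 7 without CF2, 10 without RR1, 15 without PR1. PR against its parents gave 0 to 14. It was 0 without PD1, MS1, MS2, CF1, CF2 or CF3, 1 without FL2, 2 without PD3, 3 without FL1, RR3 or PR2, 4 without RR2, 5 without RR1, 14 without PR1.

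Of the 74 named gene values 17 passed. Under the settings other than leaving out 1 array, 779 values kept direction and side of the threshold, 64 newly passed, 42 no longer passed and 2 changed sign, NELFCD in CF against PR (0.0178) and in PR against the rest (-0.10) with the cell cycle mean as a covariate. Over all 18 fits without 1 array, 1165 kept them, 17 newly passed, 142 of 306 no longer passed and 8 changed sign, all CTSZ or NELFCD in PR against the rest, down to -0.0129 and -0.18 without PR2. CTSZ ran up to 0.17 without PR1. DBX2 in PR against the rest passed without any 1 array (1.55 to 1.70, highest adjusted p = 0.0316). The 131 list calls were 112 to 151 with 1 array left out, 119 after quantile normalization, 125 after centring and 98 with the cell cycle mean as a covariate, where 55 of the 131 kept their direction and call and 12 took the opposite direction, whether they passed or not. With HINTW as a covariate 95 kept them and 6 took the opposite direction, and without RR1 it was 95 and 6 as well. Without PD2, RR3 or PR1, 1 each took the opposite direction. They were 0 with an estimated correlation and 4 with fry. The scalings moved the median of all probe sets by over 0.1 in FL against RR (-0.21 by quantile normalization, -0.25 by centring), PD against MS (-0.13 by centring), FL against the rest (-0.16 and -0.20), PD against the rest (-0.10 and -0.11), PR against the rest (0.10 by quantile normalization), RR against the rest (0.10 by centring) and CF against its parents (0.16 and 0.19). No signal over background was used here, so the level under which a difference cannot be read is not known.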

Other observations

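The tests of the W chromosome signal, those of the EDN3 region and the relations among cell type lists were chosen only after the results were seen, while the breed position tests and the splits of the arrays were fixed before. The cut of the position tests, an unadjusted p under 0.01, was not fixed in advance. It was used because almost no probe set passed after adjustment.

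Cell cycle genes varied within groups together with B cell genes. Across the 18 arrays the mean level of the cell cycle list followed that of the B cell list (Pearson r = 0.974, Spearman rho = 0.905, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 6e-05), and with group means removed r was 0.981. T cell markers ran the other way (r = -0.742, permutation p = 0.00064, adjusted p = 0.00156; rho = -0.86, permutation p = 3e-05, adjusted p = 9e-05), as did epithelial markers (r = -0.728, permutation p = 0.00078, adjusted p = 0.00156; rho = -0.798, permutation p = 0.00018, adjusted p = 0.00036). The matrix list gave r = -0.591 (permutation p = 0.00987, adjusted p = 0.0144) and rho = -0.705 (permutation p = 0.00125, adjusted p = 0.00187). The macrophage list gave r = -0.582 (permutation p = 0.012, adjusted p = 0.0144) and rho = -0.701 (permutation p = 0.00202, adjusted p = 0.00242). The endothelial list gave r = -0.506 (permutation p = 0.0333, adjusted p = 0.0333) and rho = -0.664 (permutation p = 0.00356, adjusted p = 0.00356). These 6 relations were all that were computed, their lists share 0 genes, and without RR1 and CF1, farthest from the median of the cell cycle list, r was 0.957, -0.751, -0.768, -0.459, -0.464 and -0.487 in the same order. No batch is given in the labels, so no value within batches was computed.

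PCF11, a gene of transcript 3' end processing, has 2 probe sets. One (15555534) stood at 5.22 ± 1.31 (SD, n = 3) in CF against group means of 9.33 to 10.02 elsewhere (-4.46, limma, adjusted p = 8.41e-05), and the other (15396383) at 8.80 ± 0.17 in CF (-0.28, adjusted p = 0.327).

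The W chromosome signal in 9 arrays labelled male was weighed first. Cross-hybridisation of the HINTW probe set alone is argued against by 8 of the 13 other W genes, which separated the same 9 arrays. A small share of female RNA in male samples is argued against by the Z genes, since the highest Z minus autosome difference of the 9 arrays lay below the lowest of the others (-0.19). Female birds under a male label may account for it, as all 9 arrays lay below every other array in that difference. A large share of female tissue in a sample stays open, and no group of the design gives a biological explanation to test.

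EDN3 and neighbouring genes were high in PR. A fault of the EDN3 probe set alone is argued against by 3 other members of the region that passed over the list alone, and cell make-up along the cell cycle axis by a difference of 1.38 (SE 0.172, adjusted p = 0.00866) with the cell cycle mean as a covariate, against 1.42 (SE 0.198) without. The sex make-up of the groups is argued against as the whole cause by a difference of 1.41 (SE 0.259, adjusted p = 0.229) over all 18 arrays with HINTW as a covariate, and without the 9 arrays high in HINTW, a choice made by a measured level, it was 1.25 (1.252, SE 0.281, adjusted p = 0.793), both with wider errors that ended the call. A change shared by the genes of the segment stays a candidate explanation. Of 10840 runs of 6 neighbouring genes, 33 (0.304%) had a mean difference as high as the 6 members other than EDN3 (0.51). The list had already been seen to be high in PR, and the runs overlap and include the region, so this rank is no separate support. ZNF831, PRELID3B and TUBB1 differed by 1.06, 0.69 and 0.44, but CTSZ and NELFCD by 0.09 and 0.02. ATP5E stood at 9.93 in PR but at 10.16 in RR. A breed difference in copy number or regulation was not tested here.

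Which breed FL, CF, RR and PR are could not be settled. If the breed field were right, CF would lie between PD and FL, and over 59 probe sets at an unadjusted p under 0.01 its median position was 0.576, with MS at 0.498, RR at 0.469 and PR at 0.477. PD and FL differed at an unadjusted p under 0.05 in 390 probe sets (1.87%, limma), no more than chance alone could give. The 59 were also picked by the PD and FL values themselves, so this position cannot decide on the breed field. If the initials were right, PR would lie between PD and RR, and over 626 probe sets its position was 0.555, with CF at 0.66, MS at 0.381 and FL at 0.149. The readings cannot be told apart, since unrelated groups lay midway as well. CF was farther from the mean of its parents (median absolute difference 0.353) than PR (0.182), unlike part of what the breed field predicted. However, CF held 3 arrays high in HINTW against 1 in PD and 2 in FL. Its cell cycle deviations of -1.40, -0.02 and -1.17 also lay below every PD and FL array (0.06 or more). Neither was held fixed, so the distance does not decide between the readings. If FhaLuang and CheeFah were black-boned, the initials would put EDN3 higher in FL and CF, where it differed from RR and PR by -0.79 (adjusted p = 0.206), and TYRP1, EDNRB2, TYR and DCT by -0.40, -0.22, -0.20 and -0.18. These means join unlike pairs. EDN3 differed by -1.89 in CF against PR but by 0.30 (SE 0.256) in FL against RR. In FL against RR TYR differed by 0.25, and TYRP1, EDNRB2 and DCT by -0.14, -0.04 and -0.04.

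Other splits of the arrays into groups of the same sizes were counted with the real one included. For PR against the rest 3 of 100 gave as many probe sets as the real 14 (highest other 20), for CF against its parents 2 of 100 as many as 3 (highest other 25) and for PR against its parents 3 of 100 as many as 9 (highest other 401). Each share lay under 0.05 with its count taken alone. They were the smallest of the shares given here and no correction was made over the counts, so chance is not excluded for them. PR against its parents also gave 0 with the replicate number as a block and without PD1, MS1, MS2, CF1, CF2 or CF3. The 401 points to a structure of the samples, which was not identified by a test. Chance could not be excluded, even with each count taken alone, for the F test (7 of 100, real 5, highest other 2617), PD (23, real 1, 2015), FL (11, real 2, 58), MS (100, real 0, 561), CF (13, real 2, 5495) and RR (6, real 4, 1073) against the rest, or the sum over 15 pairs (13, real 39, 15975), where the largest counts also point to a structure of the samples. Nor could it for the gene lists, with 52 of 100 splits giving as many as 131 calls (highest other 206), or per group for PD (60, real 13, 28), FL (55, real 15, 31), MS (78, real 9, 28), CF (21, real 21, 32), RR (38, real 17, 32) and PR (63, real 13, 30). Pairs of groups have 10 splits, too few for a share under 0.05. PD against MS gave 1 probe set (4 splits as large, highest other 2) and 9 lists (8, highest other 24), FL against RR 1 (4, highest other 1) and 15 (6, highest other 24), and CF against PR 5 (1, highest other 2) and 19 (5, highest other 31).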
